A study of Bacillus subtilis with 4 samples.

How the data were processed

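The deposited files hold raw counts of sequenced fragments per gene, 1 file per library, with whole numbers that sum to a different total in each file, per the file headers and the values. Per the labels' protocols, cultures of Bacillus subtilis BY212 were poured onto frozen buffer with chloramphenicol, broken while frozen, and their ribosomes pelleted, treated with micrococcal nuclease and separated on a sucrose gradient, after which the protected fragments were selected on a gel and made into small-RNA libraries. The submitters' processing notes name cutadapt 4.0, FastQC 0.73 and Bowtie2 2.4.2. The role of each, the counting tool, its use of strand, its treatment of reads that match several places, and the genome build are not given in the sources used here. Counts of overlapping genes, of genes on opposite strands and of near-identical copies are therefore uncertain. Nothing in the labels says that replicates of a time came from separate cultures, and the protocol divides a culture over 2 tubes, so replicates of a time could come from 1 culture. The p-values therefore measure the spread between these samples, which may be partly technical.

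The files hold 4422 rows, of which 4416 matched a locus tag of the RefSeq gene table of assembly ASM904v1 and 6 did not. That table was used for names and gene types only, and no coordinates are given because the files name no build. In all, 617 rows had no count in any library. Total counts were 629452 and 620820 at 16 h and 446147 and 516552 at 64 h. At these depths 3 counts, the limit that a count of 0 allows, are 0.000477% to 0.000672% of a library. The 30 rRNA rows and 86 tRNA rows were left out of library sizes and tests. They held 2.75%, 4.27%, 7.83% and 5.27% (rRNA) and 0.756%, 0.556%, 5.31% and 0.644% (tRNA) of the counts in 16 h replicates 1 and 2 and 64 h replicates 1 and 2.

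Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, scaled by TMM (factors 1.29, 1.16, 0.770 and 0.868), and 64 h was compared with 16 h in a quasi-likelihood fit with robust estimation and no block for the replicate number. P-values were adjusted by Benjamini-Hochberg over the 2253 genes tested, with a threshold of 0.05. A design of 2 against 2 libraries leaves 2 residual degrees of freedom, and the fit shares the spread across genes. The biological coefficient of variation was 37.9%. Across genes, log CPM correlated with r = 0.937 between the 16 h libraries, 0.885 between the 64 h libraries and 0.618 to 0.658 between times. The replicates of a time were not copies of one library: a chi-square test of their counts gave 49.0 (16 h) and 48.0 (64 h) times its degrees of freedom. Fold changes are log2 values with standard errors. Where a time had no counts, a fold was computed against a floor of 3 counts per library and is a bound, and where it had 1 to 3 counts the ratio is given with its 95% counting interval.

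Gene lists were written before the data were examined, 43 lists with 1026 genes, of which 970 matched. Symbols that differ from those of the gene table were paired with it afterwards from names alone. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. A list with at least 3 tested genes entered.

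The genes named were set by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean of at least 50 CPM and libraries that do not overlap. Within each described list it takes up to 4 genes past the threshold with a mean of at least 10 CPM, or 2 genes as values only. It adds the 5 genes of largest share at each time and a fixed set on amylase, secretion, hibernation, translation, motility and sporulation. The described lists are those past the threshold, those with at least 3 genes past it and the lists on secretion stress and hibernation, a limit set after the data were seen. Genes named outside the rule are marked as such.

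The fit was tested on simulated data for the same 2253 genes, with 200 genes changed. It recovered 1.47% of genes changed by 1 on the log2 scale, 31.8% of those changed by 2 and 93.9% of those changed by 4, and called 1 unchanged gene. Changes of about 2-fold were therefore mostly out of reach in that simulation. In the data 610 genes were called. More changed genes make the adjusted threshold less strict, so recovery in the data may have been higher than simulated. With simulated lists of 20 genes, camera called the list that was moved and 0 of 40 others. Those lists held random genes simulated independently of each other. The result therefore does not show how often lists of genes that move together would be called wrongly.

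Alternatives fixed before the data were examined were other scalings (DESeq2's size factors, upper quartile, library size alone), other tests (DESeq2 1.42.0, limma-voom, the older quasi-likelihood, a minimum fold of 1.5), other filters, the 10 most abundant genes left out, rRNA and tRNA rows kept, libraries thinned to the smallest, a replicate block and each library left out. Those chosen after seeing the data were protein-coding rows only, ssrA and BSU41070 left out, and DESeq2 and limma-voom with each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.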

Results

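Ribosome-protected RNA fragments were sequenced from Bacillus subtilis BY212, a strain used to express the amylase gene amyM, grown in rich medium with repeated additions of glucose. In ribosome profiling, translation is stopped (here with chloramphenicol), RNA outside ribosomes is digested with a nuclease, and the fragments that ribosomes shielded are sequenced. A gene's count then follows both the amount of its mRNA and how densely ribosomes occupy it. There were 4 libraries, 2 taken at 16 h and 2 at 64 h of culture. The gene counts summed to 629452 and 620820 in 16 h replicates 1 and 2, and to 446147 and 516552 in 64 h replicates 1 and 2. The study was set up to look at ribosome pausing in repeated batch culture. The values used here are 1 count per gene, so they compare how many ribosome footprints each gene had at the 2 times, and positions of pausing were not analysed here.

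Protein-coding genes took 88.7% and 76.5% of the counts in the 16 h libraries and 54.3% and 76.4% in the 64 h libraries. The transfer-messenger RNA ssrA, which frees stalled ribosomes, took 3.50% (95% exact binomial interval 3.46 to 3.55) of 16 h replicate 1, 14.7% (14.7 to 14.8) of 16 h replicate 2, 22.2% (22.1 to 22.4) of 64 h replicate 1 and 10.3% (10.2 to 10.4) of 64 h replicate 2. These intervals cover counting error only. The ranking of single genes differed between libraries. In 16 h replicate 1, BSU41070 held 4.31%, liaD 3.93% and ssrA 3.67% of the counts of tested genes. By the mean of 2 libraries, the largest shares at 16 h went to ssrA, liaD, BSU41070, glnA and skfA, and at 64 h to ssrA, BSU41070, ykoJ, liaD and glnA. Among them ykoJ rose (log2 fold change 2.91 ± 0.60, SE, n = 2 libraries per time; adjusted p = 0.00957), while ssrA (1.51 ± 0.82, adjusted p = 0.202; values from 0.65 without 64 h replicate 1 to 3.12 without 16 h replicate 2, none past the threshold), liaD (-0.05 ± 0.49, adjusted p = 0.954), glnA, the glutamine synthetase gene (-0.09 ± 0.49, adjusted p = 0.914), and skfA (0.48 ± 0.48, adjusted p = 0.484) did not pass the test. BSU41070, a row that the gene table used here pairs with no name, reached 1.75 ± 0.56 with an adjusted p of 0.0492, and without 64 h replicate 1 its value was 1.28 with an adjusted p of 0.118 (0.00721 to 0.239 over all alternatives, with the call lost under 9 of 16). Without 16 h replicate 2, ykoJ had 3.57. Strand use and the counting rule are not given in the sources used here, so the counts of liaD, ykoJ and rgpA may include reads of neighbouring genes or of RNA from the other strand. Whether BSU41070 holds the amylase transgene is not given in the sources used here.

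**Figure D1:**
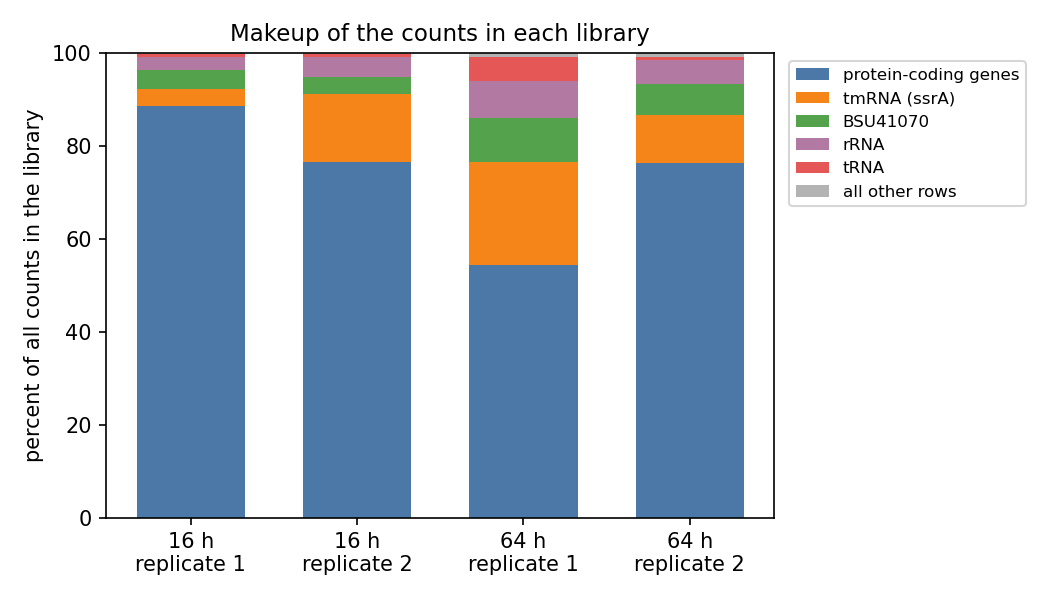
Stacked bars give the percent of all counts (vertical axis, from 0) that each kind of row took in each of the 4 libraries. Protein-coding genes took 54.3% in 64 h replicate 1 and between 76.4% and 88.7% in the other libraries.

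Some genes of gluconeogenesis and acetoin breakdown were among those that rose most between 16 h and 64 h. Central carbon genes did not change as a whole. By camera the lists of gluconeogenesis (adjusted p = 0.0919), pyruvate and overflow metabolism (0.977) and the citric acid cycle (0.720) did not pass. The glycolysis list did (0.0032), but not with an estimated correlation (0.704). The gluconeogenic genes gapB and pckA, glyceraldehyde-3-phosphate dehydrogenase and phosphoenolpyruvate carboxykinase, rose 749-fold and 357-fold, the acetoin dehydrogenase genes acoA, acoB, acoC and acoL rose 99.5-fold to 137-fold, and the glycolytic gene gapA fell (log2 fold change -2.65 ± 0.49). These large folds depend on the 64 h library used: gapB and pckA had 1214-fold and 552-fold without 64 h replicate 1, and 286-fold and 163-fold without 64 h replicate 2. The 4 aco genes had 151-fold to 207-fold without the first and 44.0-fold to 91.2-fold without the second. At the same time the lists of pyrimidine, purine, ribosomal protein and flagellar genes fell, and the lists of early sporulation genes, genes for other carbon sources, genes for amino acid and peptide uptake or catabolism and tryptophan, histidine and arginine synthesis (0 of 9 histidine genes passed) rose. None of these 8 lists passed with an estimated correlation (adjusted p = 0.385 to 0.543). In all, 2253 genes were tested, of which 309 were higher and 301 lower at 64 h, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 610 differed by at least 2-fold, and in all of them both 64 h libraries lay on the same side of both 16 h libraries. That last property held for 1482 of the 2253 genes tested, against 33.3% by chance. Of 43 gene lists written down before the data were examined, 7 were higher and 8 lower at 64 h by camera, which asks whether a list's genes rank apart from the other genes. None of these 15 passed when the correlation between genes was estimated instead of preset. Some estimates lay below the preset 0.01, as for ribosomal protein (-0.0186) and pyrimidine genes (-0.0209), and others far above it, as for ATP synthase (0.874). With an estimated correlation, camera rests on the 2 residual degrees of freedom. The loss of all 15 calls therefore does not show that correlation between genes accounts for the list results. Leaving out 16 h replicate 1 or 16 h replicate 2 left 0 genes past the threshold in either direction by edgeR, with 584 and 618 genes at an unadjusted p under 0.05. DESeq2 called 125 higher and 58 lower without 16 h replicate 1, and 151 higher and 82 lower without 16 h replicate 2. Without the TMM factors the median of all genes moved to -0.58 on the log2 scale and 28.5% instead of 50.7% of the calls were in the higher direction, so changes are given relative to the TMM-scaled median of -0.003. Of 133 named genes past the threshold, 68 had a fold that moved by over 1.5 times when 1 library was left out, and all 133 kept their direction. Since the libraries of all called genes did not overlap between times, leaving 1 out could hardly reverse a direction. Counts of lost calls given for single genes include the fits without either 16 h library, where every call was lost.

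**Figure D2:**
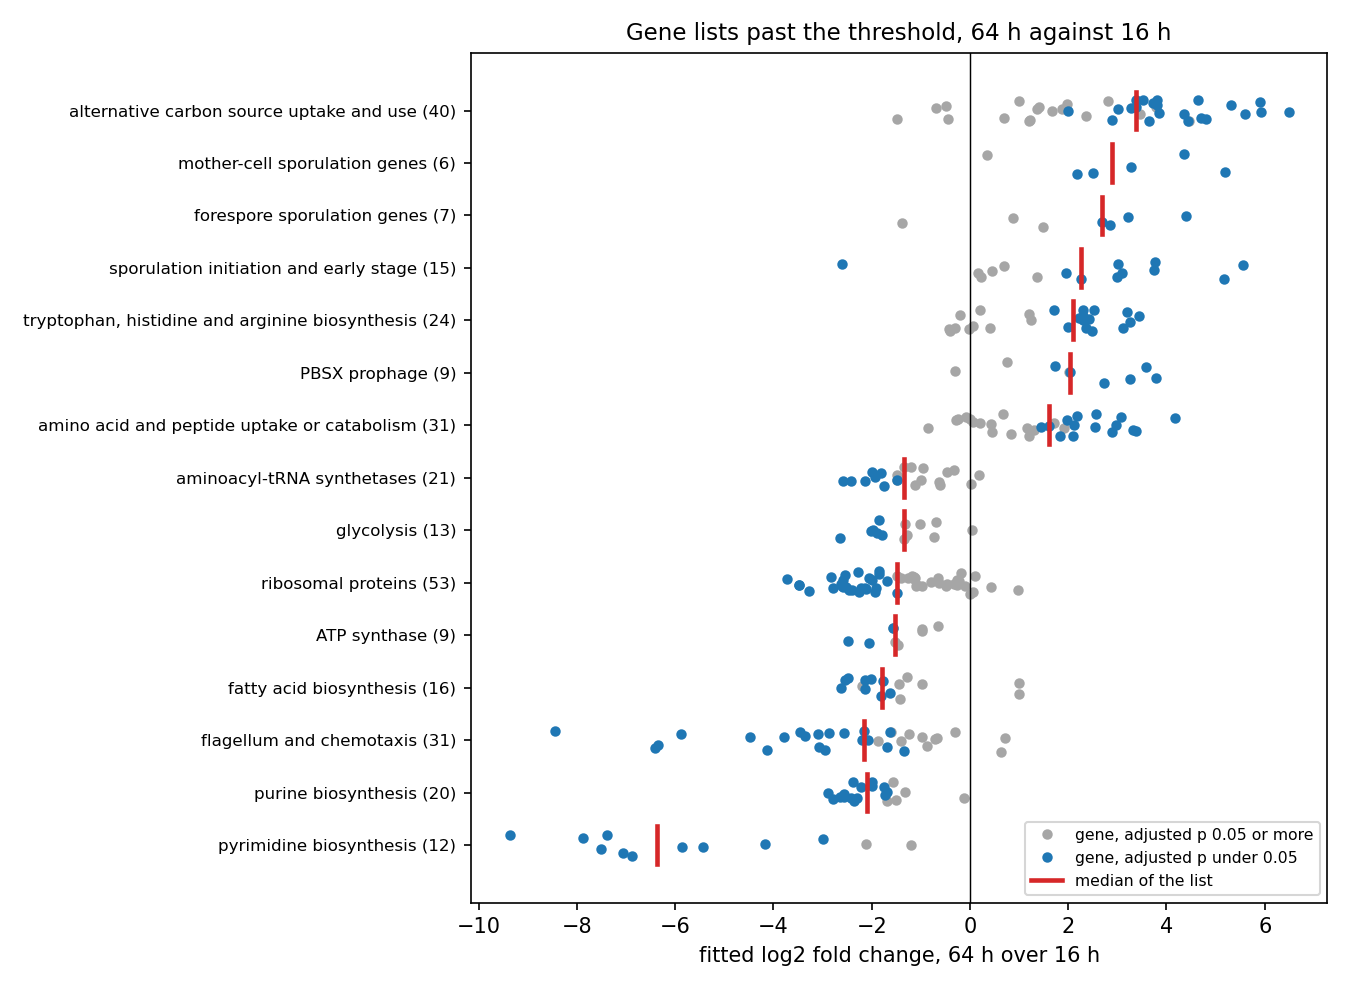
Each point is a gene's fitted log2 fold change, 64 h over 16 h (horizontal axis), in the 15 gene lists past the threshold, with the number of genes tested in parentheses, blue where the gene itself passed and grey where it did not, and a red bar at the list's median. Medians run from -6.37 for pyrimidine biosynthesis to 3.38 for alternative carbon sources.

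As lists, glycolysis genes fell, with 6 of 13 past the threshold, and genes for other carbon sources rose, with 22 of 40. Neither list passed with an estimated correlation (adjusted p = 0.704 and 0.443). Of the 13 glycolysis genes tested, 6 fell and 0 rose (median log2 fold change -1.34, camera adjusted p = 0.0032, adjusted p = 0.704 with an estimated correlation), or 9 and 0 adjusted over the list alone. The genes tpiA (-1.98) and pgm (-1.88) fell too, with 5 and 6 of 19 alternatives ending the call. Without 16 h replicate 1 these had -1.16 and -1.15. Both calls were lost without 64 h replicate 1 (-2.25 and -1.50), and that of tpiA without 64 h replicate 2 (-1.76). Normalised counts of gapA were 7065 and 4628 CPM at 16 h and 831 and 1028 CPM at 64 h. The glucose transporter gene ptsG fell by 2.01 on the log2 scale (SE 0.43, adjusted p = 0.0114). Of 7 gluconeogenesis genes, 2 rose and the list did not pass (adjusted p = 0.0919). Those were gapB (BSU29020; 9.55 ± 0.98, adjusted p = 0.00148), with 7.77 and 4.40 CPM at 16 h and 1827 and 7710 CPM at 64 h, and pckA (BSU30560; 8.48 ± 0.84, adjusted p = 0.00148). Of the 40 genes of alternative carbon source uptake and use, 22 rose and 0 fell (median 3.38, adjusted p = 1.75e-10, adjusted p = 0.443 with an estimated correlation), or 29 and 1 adjusted over the list alone. The glycerol kinase gene glpK rose by 6.49 ± 0.64 and the glycerol facilitator gene glpF by 5.90 ± 0.61. The C4-dicarboxylate transporter gene dctP rose by 5.92 ± 0.70. For the xylose isomerase gene xylA there were 3 counts at 16 h and 84 at 64 h, a ratio of 57.0 (95% interval 18.8 to 282, counting error only). Without 64 h replicate 1 the median of this list was 1.35 and its adjusted p 8.66e-09 (1.71e-12 to 0.443 over all alternatives). The list's genes together took 0.221% of the protein-coding counts at 16 h and 1.73% at 64 h (means of 2 libraries), the latter from 2.47% and 0.998% in 64 h replicates 1 and 2. Single values moved too: without 16 h replicate 2, dctP had 6.97 and glpF 6.78, and without 64 h replicate 2, gapB had 8.16, pckA 7.35 and glpK 5.83. Whether the samples were taken before or after the glucose additions due at those times is not given in the sources used here.

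The 18 genes of pyruvate and overflow metabolism split, with 5 higher and 5 lower at 64 h, and the list as a whole did not pass (adjusted p = 0.977). The rising genes were acoA (6.92 ± 0.62, adjusted p = 0.00148), acoB, acoC and acoL, whose products break down acetoin, and acsA, acetyl-CoA synthetase (3.44). The falling genes were alsS (-3.53) and alsD (-3.26), which make acetoin, pta (-3.18) and ackA (-3.54), which make acetate, and pdhD of pyruvate dehydrogenase (-2.13). The call of pdhD was lost without 64 h replicate 1, at -1.79, and without 16 h replicate 1 its value was -1.39 (lost under 4 of 19 alternatives). Without 64 h replicate 1, alsS had -4.71, and without 64 h replicate 2, acoB had 5.46, acoC 6.07, acoL 5.54 and acsA 2.83. The genes acsA, alsS, alsD, pta, ackA and pdhD were named after their values were seen. Of the 9 genes tested in the list of other secreted degradative enzymes, 3 rose and 2 fell, and the list did not pass (adjusted p = 0.533). The chromosomal alpha-amylase gene amyE rose by 5.55 ± 0.71 (adjusted p = 0.00184), from 32.4 and 10.3 CPM to 665 and 1368 CPM. Without 16 h replicate 1 it had 6.57 and without 64 h replicate 2 it had 4.93. The gene bglC of that list, a row apart from that of eglS, rose by 4.18 ± 0.61 (5.13 without 16 h replicate 1). Whether its product is a secreted enzyme was not checked. The arabinanase gene abnA had 1 count at 16 h and 22 at 64 h, a ratio of 44.7 (7.23 to 1847). The xylanase gene xynA fell (-2.52 ± 0.50), as did pelA, a pectate lyase gene named after its value was seen (-2.05). The call of pelA was lost without 64 h replicate 1 or 2, at -1.76 and -2.48, and without 16 h replicate 1 its value was -1.29 (lost under 7 of 18 alternatives). The subtilisin gene aprE had 33.7 and 74.9 CPM at 16 h and 763 and 64.6 CPM at 64 h and did not pass (2.92 ± 1.02, adjusted p = 0.0705); without 64 h replicate 2 it was 3.81 with an adjusted p of 0.00247, and with DESeq2 2.99 with 0.00516 (0.00247 to 0.788 over all alternatives). The protease gene nprE had 3 counts at 16 h and 10 at 64 h, too few to test. The transgene amyM was not analysed here by name, and whether the unnamed row BSU41070 holds its counts is open.

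Nucleotide synthesis genes fell, and pyrimidine biosynthesis had the lowest median of the 43 lists. Of 12 pyrimidine biosynthesis genes, 10 fell and 0 rose (median -6.37, or -4.15 with 3 genes at their bound; adjusted p = 1.46e-10, adjusted p = 0.385 with an estimated correlation), or 11 and 0 adjusted over the list alone. The dihydroorotase gene pyrC had 223 counts at 16 h and 0 at 64 h, at least 17.6-fold lower against a floor of 3 counts per library (adjusted p = 0.00148). The carbamoyl-phosphate synthase genes pyrAA and pyrAB had 433 and 755 counts at 16 h and 1 and 6 at 64 h, which for pyrAA is a ratio of 213 (38.0 to 8427) and for pyrAB a log2 fold change of -5.87 ± 0.62 (-6.71 without 64 h replicate 1). For pyrB, the aspartate carbamoyltransferase gene, the counts were 314 and 1 (ratio 154, 27.5 to 6117), and for pyrE they were 267 and 1 (131, 23.4 to 5204). The genes pyrK and pyrP had 78 and 56 counts at 16 h and 0 at 64 h, at least 6.24-fold and 4.44-fold lower. Of 20 purine biosynthesis genes, 15 fell and 0 rose (median -2.10, adjusted p = 3.63e-07, adjusted p = 0.429 with an estimated correlation), or 18 and 0 adjusted over the list alone. The largest fall, in purN (-2.88 ± 0.68), lost its call without 64 h replicate 1 (-2.49) and had -2.01 without 16 h replicate 2 and -3.56 without 64 h replicate 2. Others were purH (-2.79 ± 0.44), purC (-2.65 ± 0.48) and purD (-2.56 ± 0.44). The genes nadA, nadB and nadC of NAD synthesis, which stood in no list, were among the 12 genes of lowest log2 fold change, with 361, 231 and 339 counts at 16 h and 2, 1 and 1 at 64 h (ratios 88.7, 24.4 to 736; 114, 20.2 to 4505; 167, 29.7 to 6602). The genes for fatty acid biosynthesis fell in 9 of 16 cases and rose in 0 (median -1.78, adjusted p = 0.000954, adjusted p = 0.600 with an estimated correlation), 11 and 0 adjusted over the list alone. Among them were fabHB, a condensing enzyme of chain initiation (-2.62 ± 0.57), and fapR, the repressor of this pathway (-2.55 ± 0.55). The others named by the rule were acpA (-2.49 ± 0.63; -1.84 and -3.75 without 64 h replicates 1 and 2) and fabL (-2.13 ± 0.55; lost without 64 h replicate 2, at -1.78, and under 4 of 18 alternatives in all).

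Genes of the translation machinery fell in part. Of 53 ribosomal protein genes, 27 fell and 0 rose (median -1.49, adjusted p = 8.46e-09, adjusted p = 0.385 with an estimated correlation), or 33 and 0 adjusted over the list alone. Their share of the protein-coding counts was 8.08% at 16 h and 3.83% at 64 h (means of 2 libraries). The largest falls among them were in rpsNA (-3.73 ± 0.60, adjusted p = 0.00412), rplL (-3.47 ± 0.54), rpsF (-3.47 ± 0.48) and rplJ (-3.28 ± 0.58). Without 16 h replicate 2, rpsNA had -2.82, and without 64 h replicate 1, rplL had -4.10 and rplJ -4.19. The gene rpsB had a value of -0.97 ± 0.46 and did not pass (adjusted p = 0.146), but did with library size alone (-1.52, adjusted p = 0.0466; 0.0466 to 0.45 over all alternatives). Of 21 aminoacyl-tRNA synthetase genes, 8 fell and 0 rose (median -1.34, adjusted p = 0.000795, adjusted p = 0.704 with an estimated correlation), or 13 and 0 adjusted over the list alone, among them thrS (-2.59 ± 0.51), tyrS (-2.42 ± 0.54), valS (-2.14 ± 0.48) and serS (-1.99 ± 0.53). Without 64 h replicate 2, thrS had -3.21, tyrS -3.15 and serS -2.81. The 12 translation factors did not pass as a list (adjusted p = 0.0998), and 3 of them fell. These were efp, elongation factor P, which relieves ribosomes stalled at proline runs (-3.23 ± 0.53, adjusted p = 0.0046), tsf (-2.56 ± 0.44) and frr (-1.98 ± 0.50, adjusted p = 0.0211; the call was lost without 64 h replicate 1, at -1.65, and under 4 of 19 alternatives in all). The elongation factor Tu gene tufA had a value of -0.79 ± 0.47 (adjusted p = 0.241). In the list of the stringent response and ribosome hibernation 0 of 9 genes passed (list adjusted p = 0.656). Its hibernation factor gene hpf had 4410 and 3181 CPM at 16 h and 2252 and 1514 CPM at 64 h (-1.01 ± 0.47, adjusted p = 0.142). With library size alone hpf passed (-1.62, adjusted p = 0.0401; 0.0401 to 0.526 over all alternatives). The (p)ppGpp synthetase genes rsh, relQ and relP had values of -0.47, -0.00 and 0.17 with adjusted p from 0.501 to 0.998, and the cold shock gene cspB had -0.22 (adjusted p = 0.754).

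**Figure D3:**
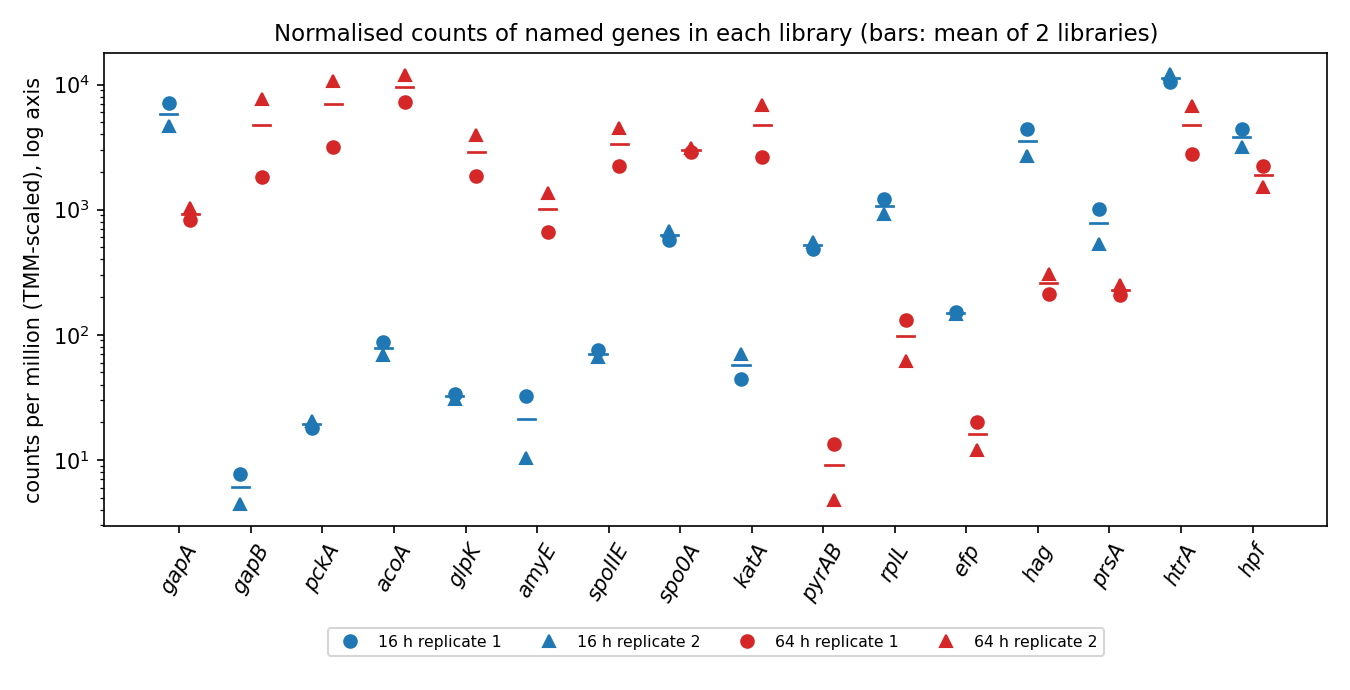
Normalised counts of 16 genes in each library, in TMM-scaled CPM on a log axis, with circles for replicate 1, triangles for replicate 2, blue for 16 h, red for 64 h and short bars at the mean of 2 libraries. For gapB the 16 h libraries lie at 7.77 and 4.40 CPM and the 64 h libraries at 1827 and 7710 CPM, and htrA and hpf did not pass the test.

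Early sporulation genes rose while most later sporulation genes had too few counts to test. Of 15 genes of sporulation initiation and the early stage, 9 rose and 1, spo0M (-2.60, named after its value was seen), fell (median 2.25, adjusted p = 3.64e-05, adjusted p = 0.429 with an estimated correlation), or 10 and 1 adjusted over the list alone. The phosphatase gene spoIIE rose by 5.57 ± 0.60 (adjusted p = 0.00148), from 75.2 and 66.1 CPM to 2252 and 4455 CPM. The processing protease gene spoIIGA rose by 5.16 ± 0.57 (5.91 without 16 h replicate 2), its substrate sigma factor gene sigE by 3.74 ± 0.47, spoIIAA by 3.77 ± 0.47 and the master regulator gene spo0A by 2.25 ± 0.45. Only 6 of 47 mother-cell genes could be tested, of which 5 rose (median 2.89, adjusted p = 0.000954, adjusted p = 0.443 with an estimated correlation; 5 and 0 adjusted over the list alone). They were spoIVA, the coat anchor (4.35 ± 0.54), spoVD (3.28 ± 0.62), spoVID (2.50 ± 0.67; 3.33 without 16 h replicate 1, and the call was lost without 64 h replicate 1, at 2.09), spoVM (2.18, named after its value was seen) and cotO, with 1 count at 16 h and 23 at 64 h, a ratio of 46.8 (7.60 to 1927). The call of spoVM was lost without 64 h replicate 1 or 2, at 2.16 and 2.23, and without 16 h replicate 2 its value was 3.47. In all it was lost under 13 of 17 alternatives, among them library size alone, the upper quartile, DESeq2 and no filter, and that of spoVID was lost under 6 of 17. The 41 untested mother-cell genes had 61 counts at 16 h and 110 at 64 h, and 13 of them had no count in any library. Such sums are not scaled. The 64 h libraries were smaller and had lower TMM factors (0.770 and 0.868 against 1.29 and 1.16), so equal sums would mean a rise. Without a filter, the median over 34 mother-cell genes was 2.27 and 8 rose (adjusted p = 0.00265; 0.000202 to 0.443 over all alternatives). Only 7 of 41 forespore genes could be tested, of which 4 rose (median 2.69, adjusted p = 0.0165, adjusted p = 0.443 with an estimated correlation; 4 and 1 adjusted over the list alone), all of the spoVA operon. These were spoVAF (4.39 ± 0.52), spoVAD (3.23 ± 0.57; 2.43 without 64 h replicate 2), spoVAA (2.84 ± 0.70; the call was lost without 64 h replicate 1, at 1.90) and spoVAC (2.69 ± 0.72; the call was lost without 64 h replicate 2, at 2.18, and without 16 h replicate 1 its value was 4.16, with the call lost under 5 of 18 alternatives). The 34 untested forespore genes had 70 counts at 16 h and 65 at 64 h, again not scaled, so these sums do not mean that they stayed level. Without a filter the median over 22 forespore genes was 1.34, with 4 higher (adjusted p = 0.0231; 0.00683 to 0.443 over all alternatives). The spore protein gene sspE had 7 counts over the libraries. The forespore sigma factor gene sigF, which stands in the early-stage list, had 1 count in all libraries together. In that list spoIIAA and spoIIAB had enough counts to test. Why sigF had almost none was not tested, so its count says nothing about forespore activity. The mother-cell list lost its call without 64 h replicate 2 (median 2.54 over 4 genes, adjusted p = 0.0626; 0.000202 to 0.443 over all alternatives), and the forespore list without 64 h replicate 1 (median 1.16, adjusted p = 0.07; 0.00683 to 0.443 over all alternatives). Mother-cell genes took 0.0138% of the protein-coding counts at 16 h and 0.0564% at 64 h, and forespore genes 0.0323% and 0.113% (means of 2 libraries).

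Flagellar genes fell. Of 31 genes of the flagellum and chemotaxis, 20 fell and 0 rose (median -2.16, or -1.87 with 3 genes at their bound; adjusted p = 1.43e-08, adjusted p = 0.429 with an estimated correlation), or 22 and 0 adjusted over the list alone. The flagellin gene hag fell by 3.77 on the log2 scale (SE 0.54, adjusted p = 0.00252), from 4447 and 2670 CPM to 213 and 306 CPM. The filament cap gene fliD had a log2 fold change of -4.12 ± 0.52. For fliS the counts were 137 and 1 (ratio 67.4, 11.9 to 2680), and for lytF they were 99 and 2 (24.3, 6.56 to 204). The chemoreceptor gene tlpA had 117 counts at 16 h and 0 at 64 h, at least 9.31-fold lower. The list took 1.00% of the protein-coding counts at 16 h and 0.194% at 64 h (means of 2 libraries). The gene of the biofilm fibre protein TasA, tasA, went from 303 counts to 2, a ratio of 74.5 (20.4 to 618). Its biofilm list did not pass by camera (1 higher and 1 lower of 4, adjusted p = 0.544). With fry it passed as lower (adjusted p = 0.0384; 0.0384 to 0.706 over all alternatives). The 15 untested biofilm genes had 62 counts at 16 h and 1 at 64 h, sums not scaled for library size.

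Genes for amino acid and peptide uptake or catabolism rose as a list. Of 31 genes of amino acid and peptide uptake or catabolism, 15 rose and 0 fell (median 1.62, adjusted p = 3.64e-05, adjusted p = 0.443 with an estimated correlation), or 17 and 0 adjusted over the list alone. The dipeptide transporter genes dppB, dppD and dppE rose by 3.33 ± 0.56, 3.39 ± 0.52 and 3.08 ± 0.46, and the arginine permease gene rocC by 4.18 ± 0.59. Without 64 h replicate 2, dppB had 2.73. Of 24 genes of tryptophan, histidine and arginine biosynthesis, 14 rose and 0 fell (median 2.10, adjusted p = 3.64e-05, adjusted p = 0.543 with an estimated correlation), or 16 and 0 adjusted over the list alone, among them trpD (3.45 ± 0.54), trpC (3.13 ± 0.65; 1.91 without 64 h replicate 1), argD (3.26 ± 0.58) and carA (3.19 ± 0.53). Without 1 library, trpD had 4.05 (16 h replicate 2), argD 4.17 (16 h replicate 1) and carA 2.55 (64 h replicate 1). Split by pathway after the values were seen, 6 of 6 tryptophan and 8 of 9 arginine genes rose, but 0 of 9 histidine genes passed (median -0.02, values from -0.44 to 1.25). The branched-chain list (adjusted p = 0.977, 0 of 11 genes past the threshold) and the sulphur amino acid list (adjusted p = 0.544, 0 higher and 1 lower of 14) did not pass. Of 9 testable genes of the defective prophage PBSX, 6 rose and 0 fell (median 2.03, adjusted p = 0.0032, adjusted p = 0.443 with an estimated correlation; 6 and 0 adjusted over the list alone), among them xkdE (3.79 ± 0.82), xhlB (3.59 ± 0.61), xkdG (3.25 ± 0.64; 3.99 without 16 h replicate 1) and xkdK (2.74 ± 0.45). The call of xkdE was lost without 64 h replicate 1 (2.74), and it had 4.88 without 16 h replicate 1 and 4.42 without 64 h replicate 2. The 22 untested PBSX genes had 87 counts at 16 h and 103 at 64 h, sums not scaled for the smaller 64 h libraries. Without a filter the median over all 31 was 1.60 with 5 higher (adjusted p = 0.00265; 0.000409 to 0.443 over all alternatives).

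The 9 ATP synthase genes passed as a list (median -1.52, adjusted p = 0.0276, adjusted p = 0.706 with an estimated correlation), with 3 lower, atpE (-2.48 ± 0.64), atpC (-2.05 ± 0.57) and atpD (-1.56 ± 0.49), which is also the count adjusted over the list alone. That call was lost without 16 h replicate 1 (median -0.90, adjusted p = 0.0848) and without 64 h replicate 1 (median -0.97, adjusted p = 0.145), and without 64 h replicate 2 the median was -2.34. Over all alternatives its adjusted p ran from 0.000988 to 0.706. Without 64 h replicate 1 the calls of atpE, atpC and atpD were lost too (-2.01, -1.84 and -1.18), and atpE had -1.57 without 16 h replicate 1 and -3.22 without 64 h replicate 2. In all, the calls of atpE, atpC and atpD were lost under 4 of 19, 6 of 18 and 8 of 19 alternatives.

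Of the secretion genes, prsA, which folds exported proteins, fell (-1.77 ± 0.48, adjusted p = 0.0267), but not without 64 h replicate 1 (-1.64, adjusted p = 0.0559; 0.0112 to 0.256 over all alternatives, lost under 4 of 19). The signal peptidase gene sipV, named after its value was seen, rose (2.02 ± 0.57, adjusted p = 0.0302). Its call was lost without 64 h replicate 1 or 2 (2.21 and 1.80) and with library size alone (1.47), and under 8 of 17 alternatives in all. With 1 higher and 1 lower of 18, the secretion list did not pass (adjusted p = 0.533). The quality-control protease genes htrA and htrB, which answer secretion stress, did not pass. The gene htrA had 10522 and 12027 CPM at 16 h and 2809 and 6682 CPM at 64 h (-1.25 ± 0.55, adjusted p = 0.12; without 64 h replicate 2, -2.01 and 0.021, and with library size alone, -1.79 and 0.0482, with 0.021 to 0.39 over all alternatives), and htrB had 0.01 ± 0.45 (adjusted p = 0.986). The secretion stress list of 4 genes did not pass (adjusted p = 0.544). Of 18 oxidative stress genes 3 rose and 1 fell, and the list did not pass (adjusted p = 0.202). The vegetative catalase gene katA rose by 6.37 ± 0.71 (adjusted p = 0.00148), from 44.1 and 70.5 CPM to 2634 and 6854 CPM (5.52 without 64 h replicate 2), and msrB, a methionine sulphoxide reductase gene, by 2.04 ± 0.45. The third riser was nfrAA (2.09 ± 0.52; lost without 64 h replicate 2, at 1.43), and trxB, thioredoxin reductase, fell (-1.62 ± 0.48; lost without 64 h replicate 2, at -1.44). Of 16 iron acquisition genes 4 fell, all of bacillibactin synthesis, dhbB (-3.11 ± 0.53), dhbF (-2.81 ± 0.54), and dhbA (-2.14) and dhbC (-1.91), whose calls were lost without 64 h replicate 2 (-1.47 and -1.67; dhbA had -3.16 without 64 h replicate 1), and the list did not pass (adjusted p = 0.358). Of 23 cell envelope stress genes 1 rose, bceB (2.28; lost without 64 h replicate 2, at 1.65, and 3.14 without 16 h replicate 2), and 5 fell, and the list did not pass (adjusted p = 0.125). The falling genes were dltC (-2.85 ± 0.58; -3.62 without 64 h replicate 2), dltA (-2.13; without 64 h replicate 2, -3.30) and dltD, with 74 and 3 counts (ratio 12.1, 3.99 to 60.1), which add D-alanine to teichoic acids, and yuaI (-1.53) and sppA (-1.59), named after their values were seen. The call of yuaI was lost without 64 h replicate 1 or 2, at -1.41 and -1.65, and without 16 h replicate 2 its value was -0.98. The call of sppA was lost without 64 h replicate 2, at -1.45. With library size alone the call of bceB was lost too. Of 22 genes of cannibalism toxins and antimicrobials, skfB (1.75; lost without 64 h replicate 2, at 1.10) rose and spbC (-1.60) and pksE (-1.90), both lost without 64 h replicate 1 (-1.19 and -1.42; pksE had -2.78 without 64 h replicate 2), fell, and the list did not pass (adjusted p = 0.544). Of 29 genes of the cell wall and division, tagA rose (1.89 ± 0.44; lost with library size alone, at 1.33), murD fell (-2.93 ± 0.65), and mreB fell (-1.58; lost without 64 h replicate 1, at -1.32, and -0.998 without 16 h replicate 2). That list did not pass either (adjusted p = 0.977). Of the calls in this paragraph, those of skfB (9 of 19 alternatives), spbC and yuaI (8 of 19 each), pksE and dhbA (7 of 18 each), mreB and sppA (6 of 19 each), nfrAA and trxB (5 of 19 each), bceB (4 of 18), dhbC (4 of 19) and dltD (3 of 18) were also lost under other settings.

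The other genes among the 12 highest log2 fold changes were rgpA (9.19 ± 1.11), with 4 and 0 counts in 16 h replicates 1 and 2, ybbC (6.55 ± 0.64), the non-coding 6S RNA gene ssrSB (6.85 ± 0.71), the muropeptide-recycling gene nagZ, with 3 counts at 16 h and 220 at 64 h (ratio 149, 50.4 to 729), and the potassium export gene khtU, with 1 and 76 (155, 26.9 to 6185). Without 16 h replicate 1, rgpA had 12.62, a value against 0 counts, and without 64 h replicate 2, ssrSB had 6.18. Those among the 12 lowest were cypX (-4.55 ± 0.52), the fructosamine deglycase gene frlB (-4.52 ± 0.71) and hemAT, a haem-based oxygen sensor (-4.25 ± 0.87), which had 0 and 5 counts in 64 h replicates 1 and 2. Without 64 h replicate 1, frlB had -5.70 and hemAT -3.43, and without 64 h replicate 2 hemAT had -9.26, again against 0 counts. The 28 lists that did not pass had adjusted p from 0.0919 to 0.977.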

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

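The tests of non-coding RNA described here were chosen after the values had been seen. Signal appeared in rows that the comparison left out. In 64 h replicate 1, rRNA rows held 7.83% and tRNA rows 5.31% of all counts, and the tRNA gene trnD-Trp alone held 58.6% of that library's tRNA counts, against 50.9%, 48.2% and 43.8% in 16 h replicates 1 and 2 and 64 h replicate 2.

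Per protein-coding count, 64 h replicate 1 held more non-coding RNA than 64 h replicate 2: 3.04 times as much ssrA, 11.6 times as much tRNA, 2.09 times as much rRNA and 32.9 times as much rnpB, the RNA of RNase P. One carry-over of all non-coding RNA alike would raise these by similar factors, but the largest was 15.7 times the smallest. In 16 h replicate 2 over replicate 1, ssrA was 4.88 times as high while tRNA was 0.852 times as high. Of the genes called between the times with 4 libraries, 77.4% were also called by edgeR without 64 h replicate 1. That fit takes its spread from the 16 h pair alone, with a median absolute log2 difference of 0.395, against 0.614 for the 64 h pair. The smaller spread favours calls, so the percentage cannot decide whether the calls rest on 64 h replicate 1. The 133 named genes past the threshold all kept their direction without it, but this was nearly fixed beforehand. Their libraries did not overlap between times, so leaving 1 out could hardly reverse them. What set each of these RNAs apart stays open, fragments of free RNA that escaped the nuclease may differ by RNA, and the labels give no group that would allow a biological explanation to be tested.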

How the results depend on the processing

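In this part, leaving out ssrA and BSU41070, testing protein-coding rows only, and DESeq2 or limma-voom with a library left out were chosen after seeing the data. Of the 133 named genes past the threshold and the 15 such lists, none changed direction under the alternatives run. For the genes this was largely set by the calls, since the libraries of called genes did not overlap between times. Apart from the settings named next, 16 of those genes and 1 list lost their call under some alternative. With library size alone, 533 genes were lower (301 of them also called with TMM) and 9 named genes lost their call. Whether a replicate number marks a shared culture or day is not stated. The deviations of replicate 1 correlated with -0.061 between times, a single value over genes that cannot exclude pairing. With the replicate block 169 genes were lower and 26 named genes lost their call. Without each library in turn, edgeR called 0 to 363 genes higher and 0 to 338 lower, all 133 named genes losing their call without a 16 h library and 29 without a 64 h library; the remaining library of a time is then assumed to vary like the others. With DESeq2 those ranges were 125 to 220 and 58 to 183, with limma-voom 105 to 429 and 83 to 275, and 15 to 19 lists passed by camera without each library in turn. With an estimated correlation 0 lists passed, and with fry 8, of which 7 were also camera's. The other was the biofilm list (adjusted p = 0.0384 by fry). Camera's lists that did not pass with fry included alternative carbon sources, amino acid and peptide uptake or catabolism, and PBSX (adjusted p = 0.073 each). Others were tryptophan, histidine and arginine synthesis, fatty acid synthesis and aminoacyl-tRNA synthetases (0.0866 each). Glycolysis (0.122) and ATP synthase (0.265) did not pass with fry either. Without the 10 most abundant protein-coding genes, the flagellar share of the protein-coding counts was 1.22% at 16 h and 0.251% at 64 h. The mother-cell share was then 0.0168% and 0.0731%, and the forespore share 0.0395% and 0.146%, since the total shrank. Without a filter, 3 lists that had not passed did: translation factors (adjusted p = 0.026, with 0.026 to 0.591 over all alternatives), general stress genes (0.0173, with 0.00918 to 0.706) and gluconeogenesis (0.0241, with 0.00197 to 0.706). The last 2 also passed without some single libraries. So did the cannibalism genes (0.00683, with 0.00683 to 0.966) and the oxygen-limitation genes (5.84e-05, with 5.84e-05 to 0.999) without 16 h replicate 2, the cell envelope genes (0.0493, with 0.0493 to 0.704) without 16 h replicate 1, and the oxidative stress genes (0.0307, with 0.0307 to 0.706) without 64 h replicate 1.

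Values near 0 that had not passed changed sign; the cause was not tested. For relQ the log2 fold change was 0.0245 with DESeq2's size factors, 0.0247 with DESeq2's test, 0.0015 with limma-voom, 0.11 with 50 counts required in every library of a time, 0.0091 without the 10 most abundant genes, and -0.0878 to 0.15 without a library. For htrB it was -0.55 with library size alone, -0.12 with the upper quartile, -0.00398 with limma-voom, -0.0472 without a filter, -0.0069 with rRNA and tRNA kept, -0.0054 with the replicate block, -0.0383 with protein-coding rows only, -0.0432 without ssrA and BSU41070, and -0.25 to 0.24 without a library. Library size alone also gave -0.0818 for skfA and -0.39 for relP. With 50 counts required, liaD had 0.0612 and glnA 0.0193. Without a library, glnA ranged from -0.27 to 0.24, liaD from -0.19 to 0.19 and cspB from -0.54 to 0.14. In simulation most changes near 2-fold were not called at these totals. Thinned to the smallest library, 295 genes were higher and 278 lower, and how far depth or the spread between 2 libraries sets that limit was not tested.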

Other observations

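The gene families and tests in this part were chosen after the data had been seen, except that the glycolysis bound was written before its result. Genes sharing the first 3 letters of their symbol were tested as families with camera: 29 of 171 families passed, and 0 passed with an estimated correlation (lowest adjusted p = 0.869). Among families not yet described, 6 of 7 fad genes, which break down fatty acids, rose (median log2 fold change 3.91, adjusted p = 1.44e-05), including fadN (4.13 ± 0.48), fadA (4.75 ± 0.57) and fadE (3.91 ± 0.52). Of 13 puc genes, for the use of purines as a nitrogen source, 9 rose (median 2.15, adjusted p = 0.00039), including pucG (4.30 ± 0.52) and pucF (3.81 ± 0.57). Of 4 ntd genes, of the antibiotic sugar kanosamine, 3 rose (median 4.21, adjusted p = 0.00503), including ntdC (4.43 ± 0.51).

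Other families fell. Of 8 bio genes, 5 fell (median -2.36, adjusted p = 0.00503), including the biotin synthase gene bioB (-3.57 ± 0.60). Of 7 frl genes, for fructosamine use, 6 fell (median -2.47, adjusted p = 0.00115), including frlD (-3.48 ± 0.55). Of 7 dap genes, for lysine and peptidoglycan precursors, 5 fell (median -2.45, adjusted p = 0.0255), including dapH (-2.60 ± 0.52). Of 12 pks genes, of the polyketide bacillaene, 6 fell (median -2.06, adjusted p = 0.00334), including pksL (-2.94 ± 0.52), and of 4 gcv genes, of glycine cleavage, 3 fell (median -2.61, adjusted p = 0.0283), including gcvT (-2.24 ± 0.47). Without 1 library, bioB had -4.35 (64 h replicate 1), frlD -2.82 (16 h replicate 2) and dapH -3.30 (64 h replicate 2).

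The 16 h libraries differed in a set of genes that respond to low oxygen. The subtilosin gene sboA had 15670 counts in 16 h replicate 1 and 239 in replicate 2, lctE, lactate dehydrogenase, had 330 and 5, and cydA, of the cytochrome bd oxidase, 218 and 4. One amplified fragment is argued against by the rest of the subtilosin operon, since albA, albC, albD, albE and albF had a median log2 ratio of 4.15. A candidate explanation is a difference in oxygen supply between the cultures, if the replicates came from separate ones. The oxygen-limitation list, which holds none of these genes, had a median log2 ratio of 1.28 with 9 of 11 genes higher in replicate 1. That was percentile 100 of 10000 random lists matched on mean expression (95% of those between -0.42 and 0.49). The random lists were drawn gene by gene, while most tested genes of this list belong to the nas and res groups and may move together. The percentile therefore overstates the evidence. In that list fnr had 142 and 24 counts and resD 152 and 26. The labels give no oxygen value and no group for it, so this stays a hypothesis.

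The 64 h libraries differed in sugar uptake operons. In 64 h replicates 1 and 2, licB had 663 and 17 counts, bglP 1149 and 61, and mtlF 230 and 10, genes for lichenan, beta-glucoside and mannitol uptake through the phosphotransferase system. The 17 genes of phosphotransferase operons in the alternative carbon list had a median log2 ratio 2.98 above that of the list's 23 other genes (3.02 against 0.04). The 17 were grouped after the pattern was seen and include the genes that set it, so this difference is no test. Scaling of the whole library is argued against by the 23 other genes alone, of which 12 were higher in replicate 1 (values from -3.32 to 0.985). That more sugar was in use in replicate 1 is left open: the glycolysis list lay at percentile 16.9, which the limit set beforehand, 50 or lower, counts against it. That limit was set aside after the value was seen, because the median of -0.45 was inside the range of random lists (-0.74 to 0.44) and gapB and pckA were also lower there (-2.08 and -1.76). A shared signal through regulators that carry phosphotransferase domains may also be involved. The levan operon genes levD, levE, levF and levG, higher in replicate 1 in 4 of 4 cases, lay at percentile 97.5. That is too close to the limit to decide, a margin added after the value was seen. These 4 genes also form 1 operon, while the random lists were drawn gene by gene. The genes fruA, treP and treA, with log2 ratios of -0.19, -0.84 and -0.73, were not part of that test.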
